A study of Zea mays with 6 samples.

How the data were processed

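The libraries were digital gene expression tag profiles of maize leaf and root at the V3 stage, from wild-type DH4866 and its lines A17 and a55. Per the labels' protocols, mRNA was bound to oligo(dT) beads from 6 µg total RNA and cut with NlaIII, and MmeI cut 17 bp beyond the CATG site nearest the 3′ end. The tags were amplified with 15 PCR cycles and sequenced on an Illumina instrument. Each library pooled 10 plants, moved to nutrient solution as 4-day seedlings, and the leaf tip and base were removed. The labels give 1 library per group and no batch.

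The authors deposited 4 tables, 1 for each line against wild type in each tissue. Per the file headers, each holds raw tag counts per gene model, a "TPM" value for each library, a log2 ratio of the line to wild type, a p-value and an FDR. The deposited TPM values are depth-scaled tags (RPM) of the whole library without a length correction, since dividing a count by its value gave the same total for every gene. The authors' log2 ratio was recomputed from those values to within 5e-09, with 0 tags replaced by a small value. The authors' test behind the deposited p-value is not given in the sources used here, and the deposited FDR exceeded 1 for 478, 455 and 582 models in 3 of the tables. The tag mapping tool, the mismatches allowed and the genome build are not given in the sources used here. The lowest count above 0 was 2, so no model had 1 tag in a library.

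Counts were taken from the tables through the column names. The wild-type counts were identical in the 2 tables that hold them. A model absent from a table was set to 0. Library totals were those implied by count and TPM, 5691979 to 5928975 tags, so 1 tag was worth 0.169 to 0.176 TPM. For ratios, a count of 0 was set to a floor of 3 tags (0.506 to 0.527 TPM). Ratio and level intervals are exact at 95% (conditional binomial and Poisson). The tables held 17661 gene models of 16837 genes. The best protein hit in the files named a protein for 3426 models (19.4%). Other names were taken from a RefSeq table of assembly Zm-B73-REFERENCE-NAM-5.0, which matched 10506 models (59.5%) by locus synonyms and was used for names only.

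For each pair of libraries, models with at least 10 tags summed were tested with a two-sided exact conditional binomial test, Benjamini-Hochberg adjusted over all models tested. A model was called at an FDR of 0.001 or less and a log2 ratio of at least 1 in size, with a library at 0 tags set to a floor of 3 tags per library. Folds given as "at least" use this floor and are bounds under it only. They are not limits of the exact intervals, which can lie lower. A count of 2 was kept, so a model at 0 tags can show a smaller fold than a model at 2. On simulated data with counting error only, the test gave 0 false calls in each comparison and recovered 10, 41, 49 and 48 of 50 genes changed 2-, 4-, 8- and 16-fold among 9176 in A17 leaf. With the spread of the 6-library model in place of counting error, it gave 1874 false calls of 9025 models in A17 leaf, 1992 of 9351 in a55 leaf, 2449 of 11276 in A17 root and 2524 of 10906 in a55 root. The model has no replicates, so this spread also holds line effects that differ between tissues. It is too wide at least for a55, where the data gave 1796 calls in leaf and 383 in root in all. The same holds for A17 root, where the data gave 2120 calls in all. Counts with this spread, here and below, are a cautious setting and not a measure of how unchanged libraries vary. The calls describe differences between 2 libraries. The 6-library model was fitted with edgeR (quasi-likelihood, TMM, filterByExpr, tissue and line as terms, 2 residual degrees of freedom).

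There were 55 gene lists, defined by words in the descriptions and names. A list's median log2 ratio was set against 10000 random lists of the same size matched on expression in 10 bins, for lists with at least 5 measured members, as a description of these libraries. Percentiles at or below 2.5 or at or above 97.5 were counted as apart. There were 5 lists below and 3 above of 40 in A17 leaf, 10 and 2 of 40 in a55 leaf, 3 and 4 of 41 in A17 root and 1 and 5 of 40 in a55 root, where chance gives about 1 on each side. Word searches took in some unintended members, such as a bZIP factor in the iron and metal list and heat shock factors beside chaperones.

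Genes were named by a fixed rule. It took the auxin efflux carriers, the 6 largest rises and 6 largest falls among called models with at least 30 tags and a described protein, and 2 called members of each list with at least 2 calls. It also took 3 models shared and 3 opposite between lines per tissue, and up to 5 called in all comparisons. Ranking used ratios with 3 tags added to each library. Because the list part named many genes, the text was narrowed, after the data were examined, to lists with at least 6 calls (2 in a55 root). The auxin lists were described for the comparisons with wild type.

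The design, gene lists, naming rule and alternatives were fixed before the data were examined. Alternatives were TMM and DESeq2 scaling, filters of 0 and 50 tags, assumed coefficients of variation of 0.1, 0.2 and 0.4 and the common dispersion of the 6-library model in edgeR's exact test, a log2 ratio of 2, an FDR of 0.05, and the authors' deposited FDR with their log2 ratio. Scaling to the tags assigned to gene models, leaving out models at 0 tags in 1 library, the simulation with the spread of the 6-library model, the scan of annotated processes, the count of models per chromosome, the random 20 Mb segments drawn for it (2000 sets), the list counts between the wild-type libraries, the intervals on 2 closing tests and the list counts under other scalings were added after the data were examined. Overlap between lines was simulated with 100 draws. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.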

Results

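The data were 3′-end tag counts from maize (Zea mays), inbred line DH4866 and 2 transgenic lines derived from it. ZmPIN1a encodes a PIN-family auxin efflux carrier, a membrane protein that moves the hormone auxin out of cells. Per the labels, line A17 carries a sense and line a55 an antisense ZmPIN1a transgene. Leaf and root were collected at the V3 seedling stage, and each of the 6 libraries (wild type, A17 and a55 in each tissue) was made from 10 pooled plants. There was 1 library per group, so no difference below has a replicate check. Each test compares the tags of 2 libraries, not the conditions, and the intervals of ratios and levels cover counting error only. Intervals of list medians and of the closing tests measure the spread between gene models, treated as independent, and not the spread between libraries. "Called" means past both thresholds (FDR of 0.001 or less, and a log2 ratio of at least 1 in size). "At least" before a fold means that a library without tags was set to the floor given in the methods. Such a fold is a bound under that floor only, and the lower limit of its exact interval can be smaller.

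Library totals ranged from 5691979 tags (leaf library labelled A17) to 5928975 tags (leaf library labelled a55), of which 28.8% to 32.0% were assigned to 17661 gene models. In leaf, 11559 models were detected in wild type, 10472 in the library labelled A17 and 11787 in that labelled a55. In root, 13773, 13773 and 13521 models were detected. The 100 most abundant models took 43.5% of the assigned tags in wild-type leaf, 55.02% in the leaf library labelled A17 and 37.5% in that labelled a55, against 28.2% to 29.4% in root. Across gene models, log2 TPM (depth-scaled tags, plus 1) correlated at r = 0.972 between wild type and a55 in root, 0.885 between wild type and A17 in root, 0.926 between wild type and a55 in leaf and 0.854 between wild type and A17 in leaf, over all models. Genes are not independent replicates.

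The targeted gene was ZmPIN1a (GRMZM2G098643_T01, chromosome 9, 3596244 to 3599652 in the files' coordinates, whose genome build is not given in the sources used here). It had 34 tags in wild-type leaf (5.74 TPM, 95% interval 3.97 to 8.02), 14 in the leaf library labelled A17 (2.46, 1.34 to 4.13) and 22 in that labelled a55 (3.71, 2.33 to 5.62). In root the tags were 178 in wild type (30.8 TPM, 26.4 to 35.7), 209 in the library labelled A17 (36.4, 31.6 to 41.7) and 220 in that labelled a55 (38.5, 33.6 to 44.0). The ratio to wild type was 0.429 for A17 leaf (95% interval 0.213 to 0.820; exact two-sided p = 0.00838, FDR 0.0164), 0.647 for a55 leaf (0.36 to 1.14), 1.18 for A17 root (0.963 to 1.45) and 1.25 for a55 root (1.02 to 1.53; exact p = 0.0295, FDR 0.108). None of the 4 ratios passed both thresholds. By direction alone, the value in leaf went against the sense label of A17 and that in root against the antisense label of a55. Both ratios and their intervals use scaling to total tags. TMM scaling brought both nearer to 1 (log2 shift of the factors -0.36 in A17 leaf and 0.04 in a55 root). Intervals under TMM scaling were not computed, so no change from wild type is not excluded. Libraries are therefore named by their labels throughout. A 3′ tag can lie outside a transgene, and an antisense transcript can be counted elsewhere, so the tag does not check the labels of either line.

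**Figure D1:**
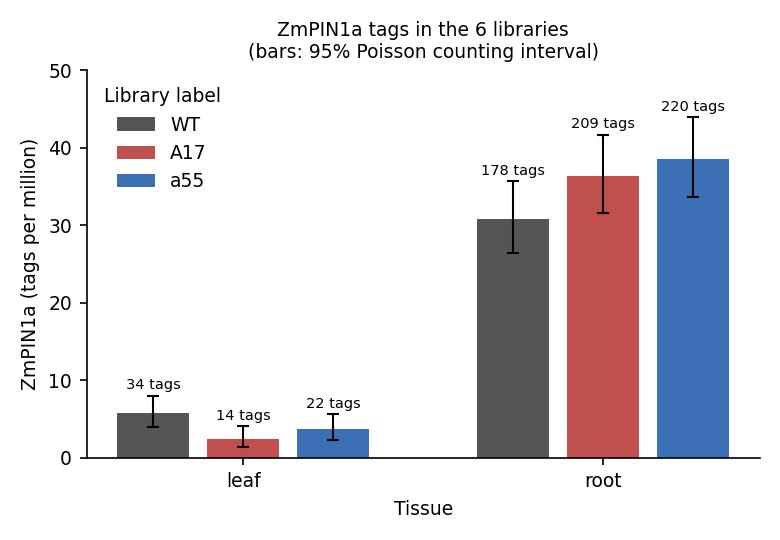
ZmPIN1a in TPM (vertical axis) in leaf and root libraries of wild type (WT), A17 and a55, with 95% exact Poisson counting intervals as error bars and 1 library per bar. Leaf values lie between 2.46 and 5.74, and root values between 30.8 and 38.5.

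The other measured auxin efflux carriers were PIN5a (GRMZM2G025742_T01, chromosome 3, 159492065 to 159496195) and GRMZM2G149184_T01, described as a putative auxin efflux carrier. PIN5a rose 2.28-fold in the leaf library labelled a55 (29 to 66 tags, interval 1.45 to 3.65), a call lost under TMM scaling, and fell 10.9-fold in the root library labelled A17 (22 to 2 tags, interval 2.69 to 95.9). It had 26 tags in the leaf library labelled A17 and 11 in the root library labelled a55, neither called. GRMZM2G149184_T01 fell at least 7.62-fold in the root library labelled A17 (23 to 0 tags) and had 20 tags in that labelled a55. The remaining auxin lists held few called members. Of 2 auxin influx carriers measured in leaf, 1 rose in the library labelled A17 and 1 fell in that labelled a55, and in A17 against a55 both were higher. Of 4 measured in root, 2 fell in the library labelled A17 (1 under TMM scaling) and 0 were called in that labelled a55. Among 14 auxin response factors, which bind auxin-regulated promoters, 1 rose and 2 fell in the root library labelled A17, and 0 of 12 were called in that labelled a55. The 6 Aux/IAA repressors measured in root gave 0 calls in either line, and of 3 in leaf 1 rose in the library labelled A17 and 0 were called in that labelled a55. SAUR genes, which respond early to auxin, gave 0 higher and 2 lower of 10 in A17 leaf, 0 and 1 of 9 in a55 leaf, and 1 and 1 of 8 in root of either line. Of the auxin synthesis genes 1 of 1 fell in A17 leaf and 1 of 3 in A17 root, and 0 were called in a55. Auxin receptors, ABCB transporters and LOB domain proteins had at most 1 measured member each and 0 calls against wild type, and 0 GH3 enzymes were measured. In leaf, 1 of 11 auxin response factors rose and 2 fell in the library labelled A17, and 0 rose and 1 fell in that labelled a55. Adjusted over the list alone, these counts did not differ.

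The wild-type leaf and root libraries differed in 5979 of 11180 tested models, 1659 higher in leaf and 4320 higher in root. Photosystem I subunit psa6 had 20495 tags in wild-type leaf and 18 in wild-type root, and the chlorophyll a-b binding protein gene cab48 had 17556 and 13. A cortical cell-delineating protein (GRMZM2G391286_T01) had 0 tags in leaf and 20288 in root, and the water channel PIP2-5 had 6 and 6581. These 4 were chosen after their values were seen. In the lists fixed beforehand, 33 of 34 light-reaction genes were higher in leaf and 0 in root, and of 7 root structure genes 0 were higher in leaf and 4 in root. Of 6 bundle sheath enzymes of C4 photosynthesis 5 were higher in leaf and 0 in root, but of 4 models in the mesophyll enzyme list 1 was higher in leaf and 2 in root. These lists were set by words in the descriptions, and whether their members are the C4 forms was not checked.

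The leaf library labelled A17 was compared with that of wild type. Pathogenesis-related proteins and WRKY factors were mostly lower in the leaf library labelled A17. Protease inhibitors (2 higher and 3 lower of 9, percentile 32.9) and benzoxazinoid synthesis genes (0 and 2 of 5, percentile 31.6) lay within random lists. PR-1 (GRMZM2G465226_T01, chromosome 7), a pathogenesis-related protein of the class secreted during pathogen attack, fell from 4846 to 2 tags (2327-fold, interval 644 to 19219), and pathogenesis-related protein 6 fell from 439 to 3 tags (141-fold, interval 47.8 to 684). Of 13 measured pathogenesis-related proteins 9 fell and 0 rose, with a median log2 ratio of -3.39 (percentile 0.00 among random lists of matched expression). Of 23 WRKY transcription factors, which regulate many defence genes, 15 fell and 1 rose (median -2.17, percentile 0.00). WRKY62 (GRMZM2G169149_T01) went from 596 to 0 tags, at least 191-fold lower, and WRKY43 from 332 to 0, at least 106-fold lower.

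The jasmonate, glutathione transferase, gibberellin, abscisic acid, cytokinin, ethylene and cytochrome P450 lists held more lower than higher calls in that library, as did all models together, and of these lists only the jasmonate and glutathione transferase medians lay outside the middle 95% of random lists. All 6 called members of the 11 in the jasmonate list fell (median -2.20, percentile 0.25). 12-oxophytodienoate reductase 2, of the enzyme family that makes the jasmonate precursor, fell 55.2-fold (345 to 6 tags), and the ZIM-domain gene ZIM18 went from 61 to 0 tags (at least 19.5-fold). Of 16 glutathione transferases 7 fell and 1 rose (median -1.48, percentile 0.67), among them gst24, which fell 54.0-fold (281 to 5 tags), and GRMZM2G052571_T01 (165 to 0 tags, at least 52.8-fold). In the gibberellin list 6 of 13 fell and 1 rose (percentile 2.77), including gibberellin 20 oxidase 2 (GRMZM2G099467_T01), a gibberellin-making enzyme, from 1627 to 0 tags (at least 521-fold), and gibberellin 2-beta-dioxygenase, a gibberellin-inactivating enzyme, 17.3-fold (36 to 2 tags, interval 4.45 to 148). Abscisic acid genes gave 7 lower and 1 higher of 16 (percentile 7.73; 4 lower and 2 higher under TMM scaling), with the phosphatase PP2C19 at 44 and 0 tags (at least 14.1-fold) and viviparous8 11.5-fold lower (24 to 2 tags, interval 2.86 to 101). Cytokinin genes gave 6 lower and 1 higher of 18 (percentile 65.3), with cytokinin-O-glucosyltransferase 2 at 254 and 0 tags (at least 81.3-fold) and the response regulator crr2 at 22 and 2 (10.6-fold, interval 2.60 to 92.7, a call lost under TMM scaling), and ethylene genes 4 lower and 2 higher of 12 (percentile 27.6), with ACC oxidase, which makes ethylene, 6.57-fold lower (171 to 25 tags) and ethylene-responsive transcription factor 4 8.59-fold lower (501 to 56 tags). Of 19 cytochromes P450, 8 fell and 3 rose (percentile 11.7), and CYP72A26 fell 69.6-fold (145 to 2 tags, interval 18.9 to 580.4) and CYP81A9 7.20-fold (150 to 20 tags).

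In the light-reaction list of that library 10 of 35 rose and 6 fell (median 0.39, interval -0.18 to 0.74, percentile 99.6). Photosystem II reaction center W protein rose 8.27-fold (18 to 143 tags) and chlorophyll a-b binding protein 6A 5.30-fold (1320 to 6718 tags). Among chlorophyll a-b binding protein genes of closely related sequence, cab48 (GRMZM2G120619_T01) fell from 17556 to 13 tags (1297-fold, interval 758 to 2436), while GRMZM2G429955_T01, with the same best protein hit, rose from 13768 to 63658 tags (4.81-fold). How tags were assigned between such copies is not given in the sources used here, so their separate values are uncertain, and the same holds for histones and other multigene families. Of 32 cytosolic ribosomal proteins 15 fell and 0 rose (median -1.13, percentile 0.32), with 40S ribosomal protein S10 11.4-fold lower (155 to 13 tags) and 60S ribosomal protein L31 5.98-fold lower (56 to 9 tags). In the histone list 7 of 17 fell and 2 rose although the median was 0.07, and a histone H4 model (GRMZM2G349651_T02) went from 130 to 0 tags (at least 41.6-fold) and another (GRMZM2G072855_T02) from 229 to 7 (31.4-fold). The aquaporin list had 5 lower and 1 higher of 17 (3 and 2 under TMM scaling), with PIP2-3 11.4-fold lower (620 to 52 tags) and the tonoplast water channel tip4b 4.64-fold lower (203 to 42 tags). Of 20 iron and metal genes 6 fell and 3 rose, a balance that ended under TMM scaling (4 and 4), among them the iron-phytosiderophore transporter ys1, 21.3-fold lower (222 to 10 tags), and the bZIP factor CPRF-2, found only by the letters of its name, 5.54-fold lower (352 to 61 tags). Cell wall glycosidases gave 4 lower and 2 higher of 17 (3 and 3 under TMM scaling), with endoglucanase 1 14.0-fold lower (102 to 7 tags) and a polygalacturonase at 15 and 0 tags (at least 4.80-fold, a call lost under TMM scaling). The heat shock and chaperone list gave 8 lower and 3 higher of 34, a balance that turned to 5 lower and 6 higher under TMM scaling. Its largest fall was that of the mitochondrial chaperone BCS1, 123-fold (384 to 3 tags, interval 41.7 to 599), and heat shock factor protein 4 had 49 and 0 tags (at least 15.7-fold). Of 6 chlorophyll synthesis genes 2 rose and 0 fell (percentile 97.7), and of 8 homeobox factors 2 rose and 0 fell (percentile 97.515).

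Large single changes in the leaf library labelled A17 included a cyclophilin (GRMZM2G162388_T01), a protein-folding enzyme, at 5218 and 0 tags (at least 1670.3-fold lower), and leucoanthocyanidin dioxygenase, a pigment-pathway enzyme, at 713 and 0 (at least 228-fold lower). Among called models with a described protein, the largest rises were those of a model with rust resistance protein rp3-1 as its best hit (AC230011.2_FGT002, 0 to 177 tags, at least 61.4-fold), the kinase TAK14 (48.2-fold, 8 to 370 tags), a mitochondrial NADH-ubiquinone oxidoreductase subunit (44.4-fold, 3 to 128 tags, interval 14.9 to 218), 50S ribosomal protein L12-1 (41.8-fold, 12 to 482 tags), a molybdopterin synthase subunit (0 to 91 tags, at least 31.6-fold) and a late embryogenesis abundant protein (28.6-fold, 12 to 330 tags).

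Over all 9182 tested models 788 rose and 2176 fell in the leaf library labelled A17. The median log2 ratio was -0.46 and TMM scaling moved it by 0.36 to -0.09, which changed the split to 1199 higher and 1551 lower. Under TMM scaling the pathogenesis-related median was -3.03, the WRKY median -1.81 and the light-reaction median 0.75 (12 higher, 3 lower). The medians of the cytokinin list (0.03), the cell wall glycosidases (0.17), heat shock and chaperones (0.25), auxin response factors (0.31) and SAUR genes (0.17) then turned positive, as did those of the ABCB, senescence, MYB, bHLH and circadian clock lists. Adjusted over the list alone, the counts differed for WRKY factors (1 higher, 18 lower), ethylene (2 and 5), heat shock (3 and 9) and homeobox factors (1 and 0). With libraries allowed to vary as in the 6-library model, 101 calls were left.

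In the leaf library labelled a55, more defence genes fell than rose, although the intervals of the list medians crossed 0. PR-1 fell 38.2-fold (4846 to 127 tags, interval 32.0 to 45.9), endochitinase A, which degrades fungal cell wall chitin, went from 159 to 0 tags (at least 53.0-fold), and 9 of 14 pathogenesis-related proteins fell and 1 rose (median -2.25, interval -5.25 to 0.58, percentile 0.00). Of 24 WRKY factors 8 fell and 1 rose (median -0.98, interval -2.0004 to 0.55, percentile 0.00), among them WRKY62 (596 to 0 tags, at least 199-fold) and WRKY7 (5.31-fold, 244 to 46 tags). Protease inhibitors gave 5 lower and 1 higher of 10 (median -1.03, interval -4.72 to 1.64, percentile 0.16), with a Bowman-Birk trypsin inhibitor (GRMZM2G007928_T01) falling from 1679 to 28 tags, 59.98-fold, and another (GRMZM2G116520_T01) from 79 to 0 (at least 26.3-fold). Of 18 glutathione transferases 5 fell and 1 rose, with GRMZM2G052571_T01 at 165 and 2 tags (82.5-fold, interval 22.5 to 687) and GST 15 at 39 and 0 (at least 13.0-fold). Medians also lay low among random lists for brassinosteroid (0 higher and 4 lower of 7, percentile 0.03), cell wall glycosidases (0 and 4 of 14, 0.37), lignin enzymes (1 and 3 of 6, 0.62) and benzoxazinoid synthesis (0 and 3 of 5, 0.80). The same held for abscisic acid, although 0 of 16 were called (percentile 0.43), and for jasmonate, although 3 rose and 2 fell of 11 (percentile 1.18).

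Light-reaction genes were also lower in the leaf library labelled a55. Of 35 members 13 fell and 4 rose (median -0.94, percentile 0.00). GRMZM2G429955_T01 fell from 13768 to 41 tags (336-fold, interval 247 to 468) and cab48 from 17556 to 123 (143-fold, interval 119.6 to 172). Of 17 aquaporins 5 rose and 0 fell, although their median lay within random lists (percentile 81.05), with PIP2-5 20.2-fold higher (6 to 121 tags, interval 8.998 to 56.02), and in the nitrogen list 4 of 10 rose and 1 fell (median 1.26, percentile 99.8), with ferredoxin-nitrite reductase at 0 and 71 tags (at least 23.7-fold). Heat shock and chaperone genes gave 8 higher and 3 lower of 36 (percentile 99.2), including the chloroplast heat shock protein 70 (3.42-fold, 26 to 89 tags) and hsp18f (3.47-fold, 64 to 222 tags). Cytosolic ribosomal proteins gave 8 higher and 2 lower of 33, with 40S ribosomal protein S11 5.14-fold higher (7 to 36 tags) and 60S ribosomal protein L35 4.40-fold higher (10 to 44 tags), and under TMM scaling 5 were higher and 2 lower and their median of 0.16 turned to -0.0041. In the senescence and proteolysis list 6 of 17 rose and 1 fell, including autophagy protein 9 (2.999-fold, 36 to 108 tags) and the cysteine protease mir3 (14.0-fold, 2 to 28 tags, interval 3.53 to 121). Of 21 cytochromes P450, 6 fell and 0 rose, with CYP92C5 3.04-fold lower (450 to 148 tags) and CYP72A26 3.15-fold lower (145 to 46 tags), and their median of 0.04 turned to -0.12 under TMM scaling. MYB factors gave 3 higher and 3 lower of 31, the largest falls being those of MYB8 (38 to 0 tags, at least 12.7-fold) and MYBR115 (33 to 0 tags, at least 11-fold).

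Other large changes in the leaf library labelled a55 were those of the receptor kinase CRINKLY4 model GRMZM2G092776_T08 (389 to 0 tags, at least 129.7-fold lower), leucoanthocyanidin dioxygenase (713 to 7 tags, 102-fold lower) and the cell-wall-loosening beta-expansin 1a (218 to 0 tags, at least 72.7-fold lower). A ripening-related protein rose 29.99-fold (3 to 90 tags, interval 9.94 to 148), RING-box protein 1a 11.2-fold (4 to 45 tags, interval 4.10 to 43.1), the small chain of ribonucleotide reductase, which supplies DNA precursors, 8.93-fold (16 to 143 tags) and the sulfate transporter sfp1 6.78-fold (27 to 183 tags). In all, 1002 of 9481 tested models rose and 794 fell. The median log2 ratio was 0.15, which TMM scaling moved to -0.01, with 765 higher and 970 lower calls. Adjusted over the list alone, the counts were the same in these lists except for protease inhibitors (2 higher, 5 lower), glutathione transferases (2 and 5), cell wall glycosidases (0 and 5) and lignin enzymes (2 and 3). With libraries allowed to vary as in the 6-library model, 8 calls were left.

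**Figure D2:**
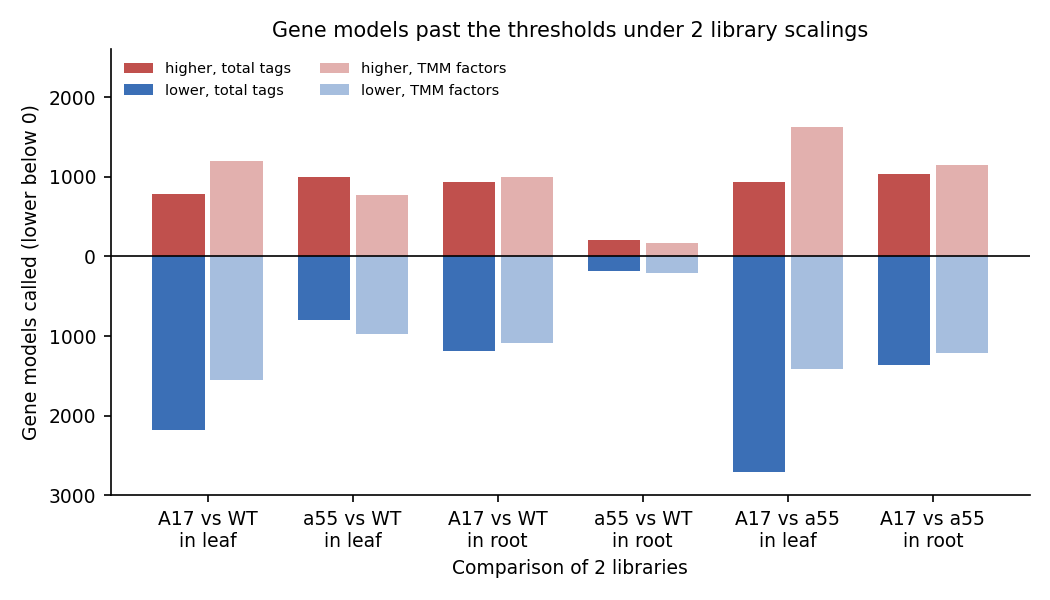
Number of gene models called higher (above 0) and lower (below 0) in 6 comparisons of 2 libraries, with scaling to total tags (dark bars) and with TMM factors (pale bars). The a55 root library gave 200 higher and 183 lower calls, against 936 and 1184 in the A17 root library.

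In root, more protease inhibitor transcripts were called higher than lower in the library labelled A17, although the interval of the list median crossed 0. Of 25 pathogenesis-related proteins 8 rose and 2 fell, with the list median of 0.21 within random lists (percentile 90.2), and with pathogenesis-related protein 10 172-fold higher (6 to 1024 tags, interval 78.6 to 469) and the chitinase chn1 18.8-fold higher (122 to 2274 tags, interval 15.6 to 22.7). Of 14 protease inhibitors 7 rose and 0 fell (median 1.03, interval -0.38 to 2.23, percentile 99.94). Among them were the wound-induced inhibitor wip1 (17.7-fold, 15 to 264 tags) and a protease inhibitor of the lipid-transfer family (7.12-fold, 169 to 1195 tags). A nonspecific lipid-transfer protein (GRMZM2G004909_T01) rose from 2 to 2820 tags, 1419-fold (interval 393 to 11724). Of 26 WRKY factors 0 rose and 6 fell, with a median of -0.03 that turned to 0.02 under TMM scaling. WRKY62 fell 19.9-fold (80 to 4 tags) and WRKY111 9.90-fold (249 to 25 tags).

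Histones were lower in that root library. In the nitrogen list 6 of 13 fell and 1 rose, with the median within random lists (percentile 2.73). The nitrate transporter gene nrt2.2 fell 77.1-fold (543 to 7 tags, interval 37.2 to 193). A model described as a symbiotic ammonium transporter, whose function was not checked, fell 7.95-fold (40 to 5 tags). Of 23 histone models 6 fell and 1 rose (median -0.67, percentile 0.11), led by a histone H3 (GRMZM2G078314_T01, 1707 to 3 tags, 565-fold, interval 193 to 2744) and a histone H4 (GRMZM2G072855_T02, 2114 to 28 tags, 75.01-fold). Peroxidases of class III, which cross-link cell walls, gave 5 lower and 1 higher of 17, with peroxidase 1 at 139 and 0 tags (at least 46.0-fold) and prx2 11.6-fold lower (653 to 56 tags). In the lignin and phenylpropanoid list 3 rose and 3 fell of 13. Caffeoyl-CoA O-methyltransferase 1 went from 236 to 0 tags (at least 78.2-fold lower) and chalcone isomerase rose 9.73-fold (12 to 116 tags). Cytosolic ribosomal proteins gave 7 higher and 1 lower of 41, including 40S ribosomal protein S21 (0 to 54 tags, at least 18.1-fold) and S18 (9.81-fold, 4 to 39 tags). Cell wall glycosidases gave 6 higher and 3 lower of 26 (percentile 98.7), with a beta-glucosidase 9.61-fold higher (11 to 105 tags) and a polygalacturonase 8.89-fold higher (6 to 53 tags), iron and metal genes 4 higher and 3 lower of 25, with a type 2 metallothionein 33.1-fold higher (91 to 2996 tags) and zinc transporter 10 14.3-fold higher (158 to 2247 tags), and glutathione transferases 4 higher and 3 lower of 18, with GST 15 35.2-fold higher (4 to 140 tags) and gst28 4.38-fold higher (149 to 649 tags). The iron and metal median of -0.03 turned to 0.02 under TMM scaling. Of 17 bHLH factors 3 rose and 4 fell, bHLH168 by 80.1-fold (484 to 6 tags) and bHLH90 by 7.44-fold (247 to 33 tags). Cytokinin genes gave 3 higher and 3 lower of 17, with cytokinin-O-glucosyltransferase 2 at 0 and 17 tags (at least 5.704-fold) and the response regulator RR4 at 0 and 15 (at least 5.03-fold). Jasmonate genes gave 5 lower and 0 higher of 13 (percentile 0.17) and cellulose synthases 2 lower and 0 higher of 13 (percentile 1.52), while phosphate starvation genes gave 4 higher and 1 lower of 11 (percentile 98.3) and late embryogenesis abundant proteins 2 higher and 0 lower of 5 (percentile 98.7). The intervals of the cell wall glycosidase, cellulose synthase, phosphate starvation and late embryogenesis abundant medians crossed 0.

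Among called models with a described protein, other large falls were those of an AMP-binding protein (GRMZM2G120539_T01, 914 to 2 tags, 454-fold, interval 125 to 3755), the cortical cell-delineating protein (20288 to 115 tags, 175-fold) and the cyclophilin GRMZM2G162388_T01 (5303 to 32 tags, 165-fold). The RING-H2 protein ATL2K rose 212-fold (4 to 842 tags, interval 82.4 to 779), a loricrin hit 208-fold (5 to 1031 tags), the mitochondrial NADH-ubiquinone oxidoreductase subunit at least 139-fold (0 to 414 tags) and a gibberellin 20 oxidase 2 model (GRMZM2G002704_T01) 129.7-fold (8 to 1031 tags). Over 11442 tested models 936 rose and 1184 fell. The median log2 ratio of -0.06 went to -0.005 under TMM scaling and to 0.005 with scaling to assigned tags. Adjusted over the list alone, the counts in these lists differed for bHLH factors (4 higher, 4 lower). With libraries allowed to vary as in the 6-library model, 70 calls were left.

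Far fewer models passed the thresholds in the root library labelled a55. Of 14 jasmonate genes 3 rose and 0 fell (median 0.74, percentile 100), with ZIM18 2.66-fold higher (73 to 192 tags) and ZIM4 2.21-fold higher (87 to 190 tags). Ethylene genes gave 2 higher and 0 lower of 16 (median 0.39, percentile 98.1), namely ethylene-responsive element binding protein 2 (4.55-fold, 8 to 36 tags) and EREB92 (2.61-fold, 415 to 1070 tags). Of 27 WRKY factors 2 rose and 0 fell, WRKY30 by 2.99-fold (40 to 118 tags) and GRMZM2G174558_T01 by 2.43-fold (240 to 575 tags). Of 22 pathogenesis-related proteins 0 rose and 2 fell (median -0.33, percentile 0.92), with pathogenesis-related protein 6 5.08-fold lower (149 to 29 tags). The nitrogen list gave 0 higher and 2 lower of 13, nrt2.2 4.47-fold lower (543 to 120 tags) and the glutamine synthetase gln3 2.02-fold lower (129 to 63 tags). Peroxidases of class III gave 0 higher and 2 lower of 17 (peroxidase 2, 2.92-fold, and peroxidase 24, 2.62-fold), tubulin and actin genes 1 higher and 2 lower of 14 (profilin A, 28 to 0 tags, at least 9.22-fold, and tubulin beta-2, 2.84-fold), and SAUR genes 1 higher (SAUR56, 2.17-fold) and 1 lower (SAUR11, 2.47-fold) of 8. In the light-reaction list psa6 rose 2.81-fold (18 to 50 tags, a call lost under TMM scaling) and lhcb5 fell 2.02-fold (94 to 46 tags). Cell wall glycosidases gave 2 higher and 1 lower of 25 (1 and 1 under TMM scaling, where their median of 0.01 turned to -0.03), with endoglucanase 1 2.03-fold higher (896 to 1794 tags, lost under TMM scaling) and glucan endo-1,3-beta-glucosidase 6 2.24-fold lower (93 to 41 tags). The phosphate starvation (1 higher of 10), cold and drought (1 of 7) and bHLH lists (0 of 18) lay high, with percentiles 98.6, 98.8 and 97.8, but the number of lists outside the middle 95% of random lists in this comparison went from 6 to 4 with a filter of 50 tags, where the bHLH median fell to 0.17.

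Single models with larger changes in that library were a polygalacturonase, a pectin-degrading enzyme (9.11-fold higher, 6 to 54 tags, interval 3.92 to 25.9), a glutaredoxin (6.70-fold higher, 13 to 86 tags), NHL25 (5.78-fold higher, 7 to 40 tags), the cold-response factor hit CBF3-like protein (4.19-fold higher, 22 to 91 tags), thioredoxin H-type 5 (4.03-fold higher, 48 to 191 tags), a phosphate-induced phi-1-like protein (4.76-fold higher, 17 to 80 tags), histone H2B.2 (6.72-fold lower, 1538 to 226 tags, interval 5.84 to 7.77), the leaf-polarity gene hit ragged seedling 2 (5.34-fold lower, 54 to 10 tags), the NAC factor ANAC010 (4.89-fold lower, 104 to 21 tags) phytochrome C1 (4.75-fold lower, 173 to 36 tags) and the glycolytic enzyme enolase 1 (4.40-fold lower, 49 to 11 tags). Over 11091 tested models 200 rose and 183 fell. The median log2 ratio of 0.02 turned to -0.02 under TMM scaling and to -0.05 with scaling to assigned tags, so no direction can be read from this split. Adjusted over the list alone, the counts in these lists differed for WRKY factors (3 higher, 0 lower) and the nitrogen list (1 and 2). With an assumed coefficient of variation of 0.2 between libraries 3 calls were left, and with the spread of the 6-library model 0.

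**Figure D3:**
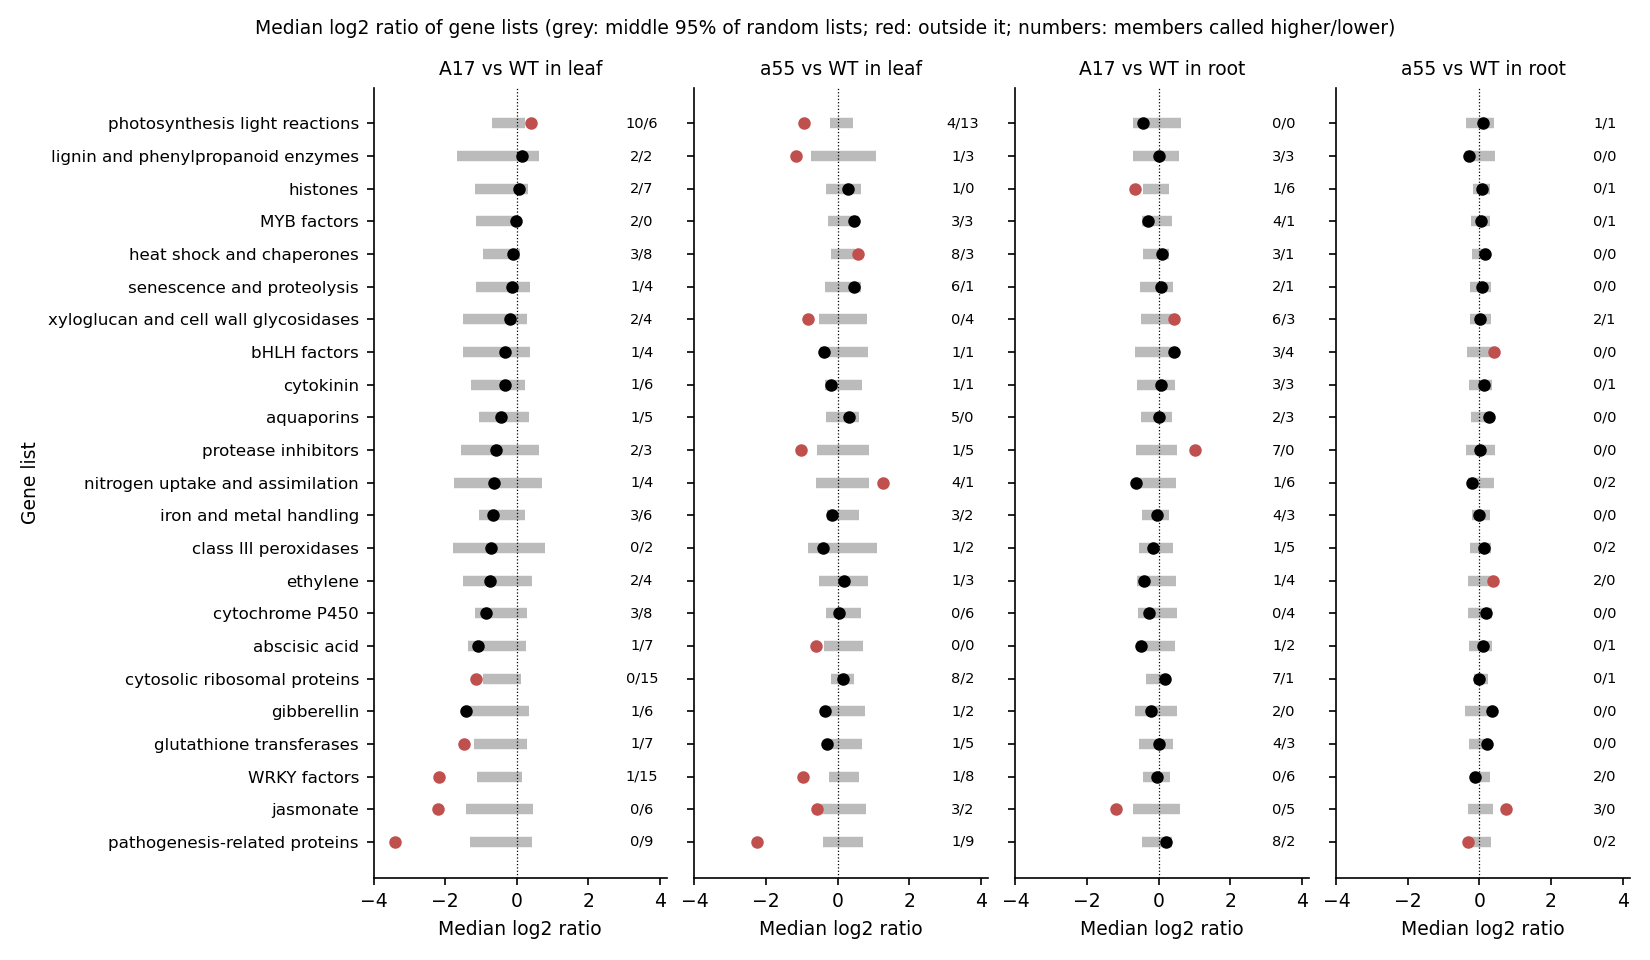
Median log2 ratio (horizontal axis) of gene lists with at least 6 called members in any of the 4 comparisons with wild type. Points are medians, red outside and black inside the middle 95% of 10000 random lists matched on expression (grey bars), and the numbers are members called higher and lower; the pathogenesis-related list lies at -3.39 in A17 leaf and 0.21 in A17 root.

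Calls shared by the lines were counted because both were compared with the same wild-type library. In leaf, 612 models were called in the same direction in both lines (135 higher, 477 lower), against 262 for independent lists, and 196 in opposite directions, against 285. Simulated unchanged libraries gave 767 shared calls against a common control with the spread of the 6-library model, which is too wide for a55. With counting error alone they gave 0. With wild-type tags divided at random into 2 parts, 449 were shared, against 190 for independent lists. The covariance of log2 ratios was 0.74 against a simulated 0.77, and the correlation across genes was 0.36 against 0.52. Those shared in leaf with the largest ratios were PR-1, cab48 and WRKY62. The largest opposite pairs in leaf were GRMZM2G429955_T01 and the undescribed models GRMZM2G144387_T02 (446, 2 and 1967 tags in wild type, A17 and a55) and GRMZM2G384884_T01 (328, 0 and 968 tags). In root, 89 were shared in the same direction against 31.8 for independent lists and 991 simulated with the spread of the 6-library model, and 50 were opposite against 32.4. That spread is too wide for both lines in root. The root covariance was 0.18 against a simulated 0.76. With the wild-type root tags divided, which also lowers their depth, 58 were shared (21.9 for independent lists) and 41 opposite (22.6), the correlation went from 0.198 to 0.0763 and the covariance from 0.18 to 0.07. Part of any excess may come from the shared control, which the design cannot separate. In root the largest shared falls were those of nrt2.2, GRMZM2G122498_T01 and GRMZM2G117971_T01, and the largest opposite pairs were GRMZM2G405017_T01, hydroquinone glucosyltransferase and GRMZM2G149935_T01.

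The tissues share no library. In A17, 701 models were called in the same direction in leaf and root, against 258 for independent lists, and 136 in opposite directions, against 209 (correlation of log2 ratios across genes 0.41). In a55, 24 were called in the same direction, against 29.0, and 74 in opposite directions, against 28.3 (correlation -0.08). There were 3 models lower in all 4 comparisons, GRMZM2G117971_T01 (4064, 0 and 760 tags in leaf and 75, 0 and 11 in root, for wild type, A17 and a55), blight-associated protein p12 (GRMZM2G099092_T01; 127, 0 and 0, then 16, 0 and 0) and GRMZM2G095663_T01 (29, 0 and 0, then 22, 0 and 0).

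**Figure D4:**
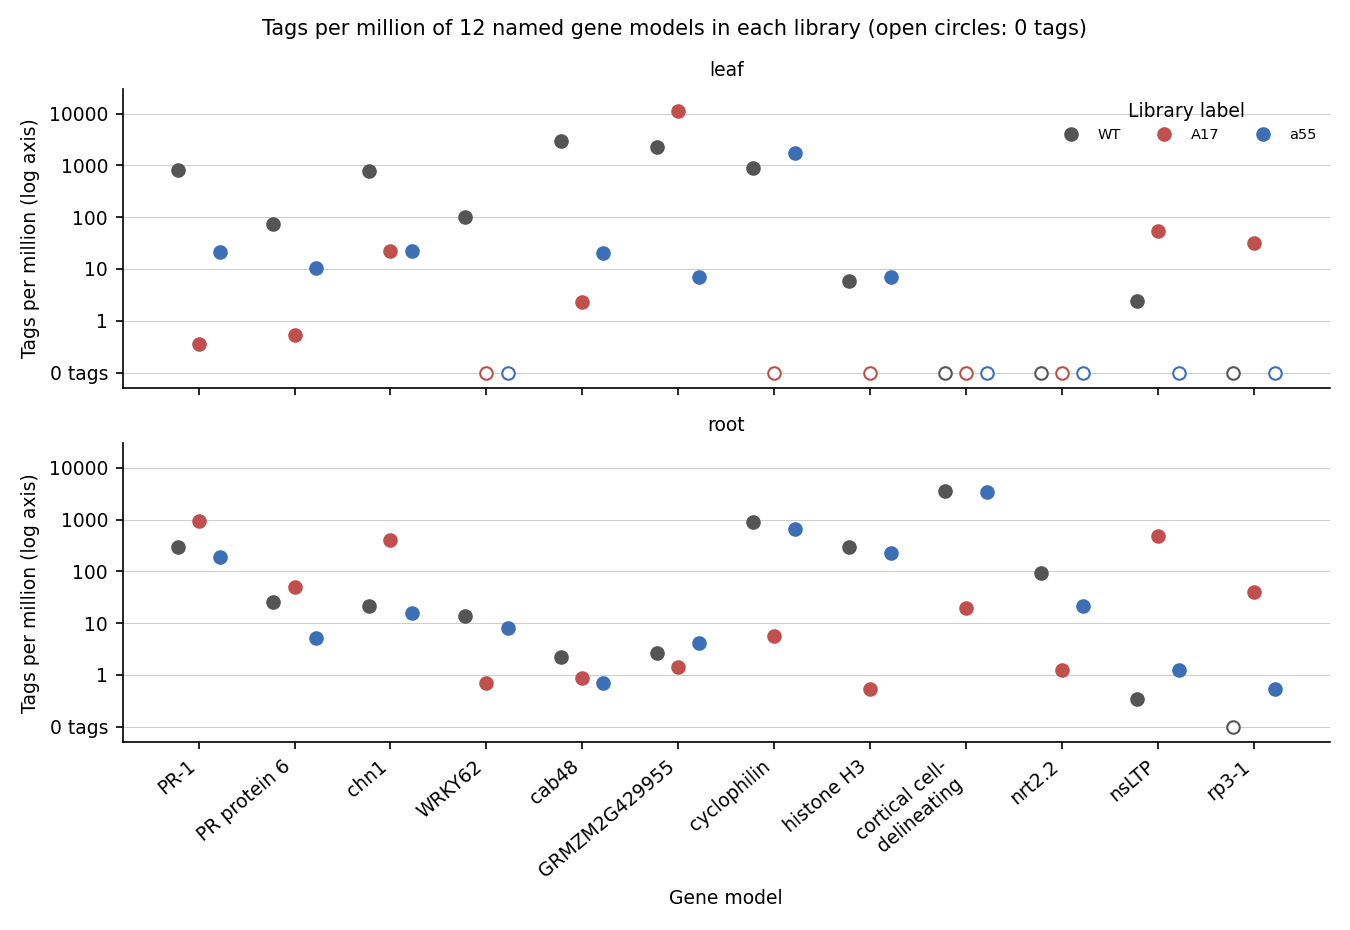
TPM (log axis, open circles at 0 tags) of 12 named gene models in leaf (top) and root (bottom), 1 library per point. PR-1 had 4846, 2 and 127 tags in wild-type, A17 and a55 leaf and 1702, 5383 and 1089 in root.

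A17 was also compared with a55, which leaves out wild type. In leaf 931 of 9242 models were higher in the library labelled A17 and 2704 lower, a split that TMM scaling changed to 1621 and 1414 (median shift 0.63). Light-reaction genes were higher (16 against 4 of 34, median 0.98, percentile 100) and cytosolic ribosomal proteins lower (0 against 19 of 33, median -1.65, percentile 0.02). The pathogenesis-related list held 1 higher and 5 lower of 10 (median -1.01) and the WRKY list 0 and 9 of 21 (median -1.11, interval -3.31 to -0.42). Both lay within random lists (percentiles 29.0 and 17.4), where the median of all models was -0.72. In root 1034 of 11395 models were higher and 1367 lower. The median log2 ratio of -0.10 went to -0.006 under TMM scaling and turned to 0.04 with scaling to assigned tags, so the split depends on the scaling. Pathogenesis-related proteins held more higher than lower calls (11 against 1 of 25, median 0.99, percentile 100), although the interval of their median crossed 0 (-0.49 to 2.11). Jasmonate genes were lower (0 against 9 of 13, median -1.56, percentile 0.02). Adjusted over the list alone, the counts differed for light-reaction (16 and 5) and ribosomal genes (0 and 20) in leaf and for pathogenesis-related proteins in root (11 and 2).

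A model over all 6 libraries had tissue and line as terms. It takes the difference of the line effects between tissues as its error, and so asks for changes alike in leaf and root. At an FDR of 0.05, edgeR's quasi-likelihood test called 0 of 10612 models in either line. At an unadjusted p under 0.05 there were 1071 for A17 and 102 for a55, and the smallest adjusted p was 0.0568 and 1. DESeq2 called 148 higher and 302 lower for A17 and 0 higher and 1 lower for a55. Among the models with the smallest edgeR p for A17 were histone H3 (GRMZM2G078314_T01), the RING-H2 protein ATL2K and a mitochondrial 2-oxoglutarate/malate carrier (GRMZM2G436593_T01; 21 and 449 tags in leaf and 13 and 498 in root, for wild type and A17). On simulated data with the estimated coefficient of variation of 0.51 the edgeR test recovered 0, 4, 22 and 35 of 50 changed genes at 2-, 4-, 8- and 16-fold.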

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

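The test of root ratios of the defence genes and its interval were chosen after those ratios had been seen. Each result here is a gene model or list whose ratio or median lay on opposite sides of 0 in leaf and root of a line. Each group is 1 library, and the difference between tissues was not tested. Log2 ratios with a library at 0 tags use the floor of 3 tags and are bounds under that floor only.

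For A17, PR-1 had a log2 ratio of -11.18 in leaf and 1.67 in root, a difference of 12.85. The chitinase chn1 had -5.15 and 4.23 (difference 9.38), and the wound-induced inhibitor wip1 -3.44 and 4.15 (7.59). The glutathione transferase GST 15 (GRMZM2G150474_T01) had -3.64 and 5.14 (8.78) and the transferase GRMZM2G052571_T01 -5.72 and 1.37 (7.09). Cytokinin-O-glucosyltransferase 2 had -6.35 and 2.51 (8.86). Each of these models also had fewer tags in a55 leaf than in wild-type leaf, so the leaf falls were not particular to A17. In wild-type, A17 and a55 leaf the tags were 4846, 2 and 127 for PR-1 and 4574, 124 and 131 for chn1. They were 34, 0 and 0 for wip1 and 39, 0 and 0 for GST 15. GRMZM2G052571_T01 had 165, 0 and 2, and cytokinin-O-glucosyltransferase 2 had 254, 0 and 45. Both lines share the wild-type leaf library. For a55, the jasmonate list had a median of -0.57 in leaf (95% interval -2.31 to 1.44, with 3 higher and 2 lower calls of 11, so its direction there is unsure) and 0.74 in root (1.31). Its member ZIM18 had -2.93 and 1.41 (4.34), endoglucanase 1 had -1.21 and 1.02 (2.23), EREB92 had -1.19 and 1.38 (2.57), and phytochrome C1 had 2.61 and -2.25, a difference of -4.86. Phytochrome C1 went the same ways in A17 (8, 55 and 49 tags in wild-type, A17 and a55 leaf, and 173, 23 and 36 in root), so this was not particular to a55.

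The defence genes were weighed further, since the medians of the pathogenesis-related and WRKY lists lay below those of random lists in leaf of both lines, although in a55 their intervals crossed 0. Loss of tags to sequence differences in A17 stays open for part of them. The 24 list members lower in A17 leaf had a median log2 ratio of -0.11 in A17 root (95% interval -1.06 to 0.32), against -4.10 in leaf, and in root 7 of them fell and 4 rose. A wild-type leaf library that alone stood apart, for example by a stress of those plants, stays open as well, since in A17 against a55 in leaf, which leaves out wild type, the WRKY list lay at percentile 17.37 and the pathogenesis-related list at 29.0, within random lists. In that comparison 9 of 21 WRKY members were lower and 0 higher in A17, and 5 of 10 pathogenesis-related members lower and 1 higher. All models together also leaned lower there (median -0.72). An effect of altered ZmPIN1a in both lines was not tested and stays open.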

How the results depend on the processing

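No paired analysis was possible because each group has 1 library and the labels give no replicate numbers, and the 6-library model blocks on tissue only. The cause of the changes below was not tested, except that wider assumed spread and stricter thresholds leave fewer calls by construction. For A17 leaf, a55 leaf, A17 root, a55 root, A17 against a55 in leaf and the same in root, in that order, the 2964, 1796, 2120, 383, 3635 and 2401 calls became 1480, 474, 939, 3, 1802 and 1108 with an assumed coefficient of variation of 0.2. They became 408, 67, 246, 0, 387 and 277 with 0.4, and 101, 8, 70, 0, 99 and 61 with the dispersion of the 6-library model. With 0.1, a55 root had 200 and the others were within 1.5 times. A log2 ratio of 2 left 1772, 747, 1226, 60, 2097 and 1381, and an FDR of 0.05 gave a55 root 741. At a log2 ratio of 2, shared calls in the same and opposite directions were 308 and 27 between lines in leaf, 14 and 3 in root, 462 and 39 between tissues in A17, and 8 and 6 in a55. The 6-library model called 0 in either line, 369 for A17 without a filter, and 450 for A17 and 1 for a55 with DESeq2. TMM, DESeq2 size factors, the total of assigned tags, filters of 0 or 50 tags, and leaving out models at 0 tags in 1 library kept each of the 6 counts within 1.5 times, as did the authors' deposited FDR for the 4 comparisons with wild type. The ratios of ZmPIN1a under TMM factors were -0.86, -0.79, 0.30 and 0.29 (log2) for A17 leaf, a55 leaf, A17 root and a55 root, on the same side of 0. Of the named gene results, 95 lost their call with a coefficient of variation of 0.4 and 67 did not, and 5 lost it under TMM factors, and 0 reversed. List medians that left the 95% interval of the main median were those of the light reactions in A17 leaf (0.75 under TMM factors and 0.85 with the median of all genes subtracted) and abscisic acid in a55 leaf (-0.77 under TMM factors). Others changed by more in size within wider intervals, such as jasmonate in a55 leaf (-0.57 to -0.25) and phosphate starvation in a55 root (0.54 to 0.18) and A17 root (0.69 to 1.24) at 50 tags, and ribosomal proteins in A17 leaf (-1.13 to -0.68 with the median subtracted). Pseudocount alternatives were not run, since the files hold counts. Depth limits models below about 10 tags, and no call has a replicate.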

Other observations

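Processes annotated in the files were scanned after the data were examined, over 80 to 92 terms with 15 to 300 tested models per comparison, of which chance puts about 2 on each side outside the middle 95% of random lists. There were 7 below and 1 above in A17 leaf, 9 and 5 in a55 leaf, 4 and 3 in A17 root and 4 and 3 in a55 root. The terms described here are among those with a percentile of at most 0.1, and none lay as far above. The term glucan biosynthetic process was low in the leaf library labelled A17 (13 of 24 lower, 0 higher, median -1.67, percentile 0.08). Among its falls were ribose-5-phosphate isomerase (90 to 26 tags), a putative glycosyltransferase (44 to 12) and cellulose synthase catalytic subunit 12 (14 to 0, near the floor). The fixed cellulose synthase list lay within random lists in that library (0 higher and 3 lower of 10, percentile 53.3). In the leaf library labelled a55, porphyrin biosynthetic process was low (8 of 23 lower, 1 higher, percentile 0.05), including the chlorophyll-pathway enzyme protochlorophyllide reductase B (50 to 14 tags, 3.57-fold lower), and so was defense response (9 of 57 lower, 2 higher, percentile 0.06), including the antifungal protein zeamatin (62 to 2 tags). The defense response term also held falls of a peptidyl-prolyl cis-trans isomerase (1348 to 359 tags) and sedoheptulose-1,7-bisphosphatase (5202 to 1886 tags). Its low median therefore cannot be read as a fall of antifungal proteins alone. In the root library labelled A17, generation of precursor metabolites and energy was low (19 of 78 lower, 5 higher, percentile 0.00), including ferredoxin-3 (31 to 0 tags, at least 10.3-fold lower).

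The tests of tag sites, of an incomplete A17 root library, of models per chromosome, of simulated segments and of abundant models in A17 leaf, and the interval on the shift without models lower in A17 root, were chosen after the results they address had been seen. In root, 65 models had at least 50 tags in wild type and 0 in A17, and 64 the reverse, while a55 had 0 and 0 (in leaf, where the pattern was not weighed, 186 lost and 11 gained in A17, and 32 and 2 in a55). An incomplete A17 root library is argued against by the 64 models gained. Chromosome segments of another origin were weighed by position. Of the models lost or gained 54.3% had another within 5 Mb, inside the 42.6% to 62.8% of random sets. Of sets drawn only from simulated 20 Mb segments over 50% of the genome, 98.8% lay above that range. This argues only against segments of that size, over up to 50% of the genome, that hold all these models. Smaller segments, or segments that hold part of the models, were not simulated and stay open. Segments over 75% of the genome are left open, as only 34.6% of sets drawn from them lay above it, and the spread over chromosomes (2 of 801 tested models on chromosome 9, 15 of 763 on chromosome 10) was more uneven than in 97.92% of random sets. A difference of the line at the tag sites also stays open, as of 41 models lost in A17 root that had 20 or more tags in leaf of wild type and a55, 37 (90.2%) had at most 2 tags in A17 leaf, although only 13 of the 38 models gained in A17 root with 20 or more tags in A17 leaf were absent from the other leaves. Graded regulation may also account for them, as of 3422 models with at least 100 tags in wild-type root 43 had a ratio under 0.01 and 48 a ratio from 0.01 to 0.05 (quotient 0.896, exact interval 0.580 to 1.38), and neither was tested on sequence.

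The median log2 ratio of -0.46 in A17 leaf was weighed against 2 explanations. Loss of tags at sequence differences stays open. Without the models lower in A17 root the median was still -0.38, a move of 16.2% of its distance to 0. The 95% interval from resampled gene models was 12.3% to 19.3%, under the bound set against this explanation. The test cannot decide, since 8302 of 9182 models stayed in. Losses in leaf models that were not tested or not called in root were not removed. A larger share of tags in a few abundant models may contribute. Without the 100 most abundant models, which held 42.7% of assigned tags in wild type and 53.9% in A17, the median was -0.14, between the bounds set for and against, so this cannot be told apart from a general change. No biological explanation of the shift was tested.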
